A study of Homo sapiens with 12 samples.

How the data were processed

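RNA from cultured primary human keratinocytes was measured on 12 Affymetrix expression arrays, 1 array per culture. Per the labels, cells of 3 keratinocyte sources were each left untreated or treated with IL-17, IL-22 or IFN-gamma, and the series' design text gives 24 hours of treatment. This makes 4 conditions with 3 arrays each. Cytokine doses and culture details are not in the labels. The sources are called source 1, 2 and 3 here, and whether each is a separate donor is not stated.

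The deposited table holds 1 value per probe set and array for 22277 probe sets. Per the submitters' processing notes, the authors made these values with GCRMA, a background correction, normalization and summary of a probe set's probes. No version was given. The deposited values were taken to be log2 expression values, since the array minima lay between 0.276 and 0.318, the medians between 3.80 and 3.98 and the maxima between 16.1 and 16.3. Before any fit, the 12 arrays were checked to be distinct, and no value was missing.

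Probe sets were named through the platform annotation. Of these, 19064 carried exactly 1 gene symbol, 1043 carried several and 2170 carried none. Entrez identifiers matched 19058 single-gene probe sets to current gene names and changed 0 symbols. Left out were 58 probe sets of X-inactivation and Y-linked genes, and 62 control probe sets. Single-gene probe sets covered 11935 genes. A probe set was kept when its log2 value reached 4 on at least 3 arrays, and a gene was represented by its kept probe set of highest mean, which left 6930 genes to test. For comparison, the 27 control probe sets for bacterial transcripts absent from the samples reached at most 2.87. Where a group lay below 4 on every array, a fold change is given as "at least N-fold", with that group set to 4, and no fold is given where the other group's mean was under 4 as well.

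The main test was limma (version 3.58.1, R 4.3.3) with lmFit and eBayes on the log2 values. All 12 arrays entered 1 fit with the condition and the keratinocyte source as terms, which left 6 residual degrees of freedom and added 2.79 prior degrees of freedom. The source was a fixed block because the labels name the source of each array. Arrays of the same source deviated together: the correlation of their deviations from the condition means ran from 0.37 to 0.82 (median 0.70, 18 pairs), against -0.73 to 0.24 (median -0.45, 36 pairs) for arrays of different sources. The 3 deviations of a condition sum to 0, so the negative values follow by arithmetic from the positive ones and add nothing to them. Counts without the block stand beside each comparison. Adjusted p-values are Benjamini-Hochberg values over the 6930 genes of a contrast, and a gene is said to have changed when its adjusted p was under 0.05.

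Before the data were examined, 21 gene lists, the rule for named genes and the alternatives were fixed. Of the 21 lists, 19 had at least 3 tested genes and were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a contrast. Camera with an estimated correlation and fry were the alternatives. A count of a list's members is given over all genes tested and, where it differs, adjusted over the list alone. The rule for named genes took, for each cytokine, the 10 largest rises and 10 largest falls among changed genes with the same sign in all 3 sources. It added up to 4 changed members per list, up to 2 members of smallest p for a list without one, the 5 largest differences each way between cytokines, and the receptor genes. Genes named outside this rule were chosen after their values were seen: FLG and DSC1 under IL-22, the genes shared between cytokines, markers of other cell types below the filter level, KRT5 and KRT14, and RHCG, NDRG2 and IL36RN under IL-17.

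The comparisons of each cytokine with the control share 3 control arrays, so shared calls and correlations are set beside 100 simulated draws of unchanged groups against those controls, and beside the overlap of independent lists. Covariances between fold changes of different sources, which share no array, were added after seeing the data. The fit was tested on simulated data with 200 genes of known change among the 6930. It recovered 96% of genes changed by a log2 value of 1 in the IL-17 contrast, 90% in the IL-22 contrast and 98% in the IFN-gamma contrast. At a log2 value of 0.5 the shares were 48%, 56% and 50%. The changed genes were drawn at random with Gaussian noise, and 200 changed genes ease the adjusted threshold. In the data, FLG under IL-22 had an estimate of -4.86 and was not called. The shares therefore do not tell what part of the real IL-17 or IL-22 changes was found.

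Also fixed at that point were these alternatives: the fit without the source block, the source as a random block, no filter, a stricter filter at 6, values under 4 set to 4, the mean of a gene's probe sets, every probe set on its own, arrays centred on their median over the tested genes, quantile normalization, eBayes with trend and robust, a fit of only the 6 arrays compared, and leaving out each source and each array in turn. Added after seeing the data were a covariate for RNA end coverage, the difference between the 3′ and 5′ actin probe sets of each array, and arrays centred on their median over all probe sets. The number of arrays limits the precision of every value. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.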

Results

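Gene expression was measured in primary human keratinocytes, the main cells of the epidermis, after 24 hours with IL-17, IL-22 or IFN-gamma or without a cytokine. IL-17 and IL-22 are products of Th17 cells and IFN-gamma is the signature cytokine of Th1 cells. The series title asks which inflammatory and keratinocyte responses the Th17 cytokines control. Each of the 4 conditions had 3 arrays, 1 per keratinocyte source. Array medians lay between 3.80 and 3.98 on the log2 scale, and between 49.4% and 49.9% of probe sets reached 4. Arrays correlated with each other at r = 0.863 to 0.992 across the 6930 tested genes.

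Transcripts of the receptors for all 3 cytokines were present in untreated cells. Log2 expression in the control was 4.39 ± 0.61 (SD, n = 3) for IL17RA and 4.86 ± 0.01 (SD, n = 3) for IL17RC, both near the level at which genes were tested. It was 7.61 ± 0.53 (SD, n = 3) for IL22RA1, 8.64 ± 0.18 (SD, n = 3) for IL10RB, 12.54 ± 0.21 (SD, n = 3) for IFNGR1 and 11.52 ± 0.07 (SD, n = 3) for IFNGR2. Keratinocytes of source 1 had a larger gap between the 3′ and 5′ actin probe sets (2.13 ± 0.28, SD over 4 conditions) than source 2 (0.94 ± 0.03) and source 3 (1.05 ± 0.30). Between conditions this gap was 1.41 ± 0.91 in the control, 1.39 ± 0.74 with IL-17, 1.42 ± 0.44 with IL-22 and 1.28 ± 0.62 with IFN-gamma (SD, n = 3).

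Most markers of other cell types did not pass the filter, but COL1A1, VIM and SPARC of the fibroblast markers were well above it. Which cells these transcripts came from was not tested. No Langerhans cell or leukocyte marker passed the filter, and PTPRC reached at most 2.55 in any condition mean. Of the melanocyte markers, MITF was tested (4.37 in the control), while MLANA, PMEL and TYR had control means of 2.47, 1.85 and 1.87. Of 14 fibroblast markers, 4 were tested: COL1A1 (9.21 in the control), VIM (12.41), SPARC (12.44) and PDGFRA (2.67). COL1A2, COL3A1, DCN and LUM had control means of 2.52, 2.76, 2.86 and 2.85.

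IL-17 raised transcripts of antimicrobial peptides, of neutrophil-attracting chemokines and of the small proline-rich family members SPRR2B, SPRR2C and SPRR3. S100A7 (psoriasin, an antimicrobial S100 protein) went from 3.54 ± 1.73 to 11.11 ± 1.11 (log2, SD, n = 3), a log2 fold change of 7.57 ± 0.42 (SE; limma, adjusted p = 9.83e-05). CCL20, which attracts CCR6-bearing lymphocytes and dendritic cells, rose by 4.82 ± 0.30 (SE; limma, adjusted p = 0.000145), and S100A12 rose by 4.94 ± 0.64. The only gene that fell was LORICRIN, a main protein of the cornified envelope (log2 fold change -2.62 ± 0.28, SE; limma, adjusted p = 0.00404). S100A7, S100A12 and CXCL6 reached 4 on 2 of 3 control arrays, and LORICRIN on 1 of 3 arrays with each cytokine.

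All 7 neutrophil and Th17 chemokines tested rose with IL-17, led by CCL20, CXCL6 (4.71), CXCL1 (2.94) and CXCL2 (2.59). Of 8 antimicrobial peptides and S100 alarmins, 6 rose, and 8 did adjusted over the list alone. LCN2, an iron-scavenging lipocalin, rose by 2.18, and PI3 (elafin), an elastase inhibitor, rose by 1.88. Among 10 activation keratins and small proline-rich proteins, 4 rose over all genes and 6 adjusted over the list alone. These included SPRR2C (at least 11.3-fold), SERPINB4 (at least 19.5-fold), SPRR2B (log2 fold change 1.78) and SPRR3 (1.38). The NF-kB and IL-17 response list had 2 risers of 10, the epidermal cytokines IL36G (3.91) and IL1B (1.40), and 4 adjusted over the list alone. In the STAT3 response list IER3 (0.79) and PIM1 (0.57) rose, 2 of 9 both over all genes and adjusted over the list alone. PDZK1IP1 (at least 8.3-fold) and the amino acid transporter SLC6A14 (log2 fold change 3.17) were also among the 10 largest rises.

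Camera placed these 5 lists higher with IL-17, and all 5 held with an estimated correlation (adjusted p = 0.00458 to 0.0404). A further 4 lists were called at the preset correlation and lost with an estimated one. The basal keratinocyte and hemidesmosome list was lower (median log2 fold change -0.19, camera adjusted p = 1.31e-05; adjusted p = 0.118 with an estimated correlation), with KRT15 at -0.69 (limma, adjusted p = 0.0665) and 1 member lower adjusted over the list alone. MHC class I genes were lower as a list (median -0.14, camera adjusted p = 0.00135; adjusted p = 0.0997 with an estimated correlation), and so were type I interferon-stimulated genes (median -0.18, camera adjusted p = 0.000824; adjusted p = 0.479 with an estimated correlation). Their members of smallest p were ERAP2 at -0.42 and IFIT1 at -0.70 (limma, adjusted p = 0.559 and 0.451). The terminal differentiation list was higher (median 0.12, camera adjusted p = 0.0231; adjusted p = 0.119 with an estimated correlation). Its changed members went both ways: ALOX12B, a barrier lipoxygenase, rose 2.82-fold, CRCT1 rose 1.91-fold and LORICRIN fell, but ALOX12B and CRCT1 passed in 8 of the 21 alternative settings (limma, adjusted p = 0.0126 to 1 and 0.00488 to 1). Adjusted over the list alone, 5 differentiation genes were higher and 2 lower. The other 10 tested lists had camera adjusted p-values between 0.145 and 0.962.

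In all, limma called 43 of 6930 genes for IL-17 (42 higher, 1 lower), of which 32 changed at least 2-fold, and 475 genes had an unadjusted p under 0.05. Without the source block the counts were 11 genes and 9 at least 2-fold. The count dropped to 17, 9 and 10 genes without source 1, 2 or 3, to 28, 26 and 21 without the IL-17 array of source 1, 2 or 3, and to 21 without the control array of source 3. It was 12 when only the 6 arrays compared were fitted. S100A7, CCL20 and PDZK1IP1 passed in each of the 21 alternative settings, while PIM1 and IL1B passed in 8 and 10 of them.

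IL-22 raised S100A7 and lowered 3 of 25 keratinocyte differentiation genes. S100A7 reached 12.38 ± 0.56 (log2, SD, n = 3), a log2 fold change of 8.84 ± 0.42 (SE; limma, adjusted p = 5.14e-05). KRT1, the type II keratin of suprabasal cells, went from 8.46 ± 0.55 in the control to 2.93 ± 0.55 with IL-22 (SD, n = 3), which is at least 22-fold lower (limma, adjusted p = 0.000268). LORICRIN fell by 3.57 on the log2 scale and CALML3, a calmodulin-like protein of epithelia, fell by 1.47. The LORICRIN estimate rests partly on background, with 1 of 3 IL-22 arrays at 4 or more, and ran from -3.96 to -2.40 in the alternative settings.

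The whole set of changed genes was 10. SERPINB4 (at least 10-fold higher), the calcium-binding S100P (log2 fold change 3.20, at 4 or more on 1 of 3 control arrays), SCG5 (1.45) and CARHSP1 (0.95) rose beside S100A7. CYP4B1, a cytochrome P450 (at least 5.45-fold lower), and TM7SF2, a sterol reductase (log2 fold change -1.78), fell beside KRT1, LORICRIN and CALML3. FLG (filaggrin, at 4 or more on 2 of 3 IL-22 arrays) and DSC1 (a desmocollin) did not pass: they were lower in all 3 sources, with estimates of 29.0-fold (95% interval of the log2 fold change -7.04 to -2.67; limma, adjusted p = 0.119) and 8.01-fold (-4.87 to -1.13; limma, adjusted p = 0.274).

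Of 25 terminal differentiation genes, 3 fell with IL-22, and adjusted over the list alone 12 were lower and 3 higher. Camera placed this list lower (median log2 fold change -0.37, adjusted p = 7.61e-08; adjusted p = 0.0275 with an estimated correlation). The antimicrobial list was higher (median 0.76, camera adjusted p = 9.11e-15; adjusted p = 0.0438 with an estimated correlation), with S100A7 as its 1 changed member and all 8 higher adjusted over the list alone. Neutrophil and Th17 chemokines were higher as a list (median 0.53, camera adjusted p = 0.024), a call lost at adjusted p = 0.693 with an estimated correlation, and CXCL1 stood at 0.73 ± 0.30 (SE; limma, adjusted p = 0.43). Matrix proteases were higher (median 0.09, camera adjusted p = 0.0468; adjusted p = 0.427 with an estimated correlation), with MMP1 at 2.26 ± 0.35 (SE; limma, adjusted p = 0.0558) and 4 members higher and 1 lower adjusted over the list alone. STAT3 itself was at 0.35 ± 0.08 (SE; limma, adjusted p = 0.164), and its response list was not called (camera adjusted p = 0.0822). The remaining lists had camera adjusted p-values up to 0.998.

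For IL-22, limma called 10 of 6930 genes (5 higher, 5 lower), 9 of them at least 2-fold, while 784 genes had an unadjusted p under 0.05. Without the source block 3 genes were called, all at least 2-fold. The count was 5, 3 and 4 without source 1, 2 or 3, and 4 without the IL-22 array of source 1, without the control array of source 1 or without that of source 3. S100A7 passed in each of the 21 alternative settings, and KRT1 in 20 of them, while SCG5, SERPINB4 and CALML3 passed in 7, 10 and 10. The count was 3 without the filter or with only the 6 arrays compared, 21 (14 higher, 7 lower) with each array centred on its median over all probe sets, 23 (14 higher, 9 lower) with the stricter filter, 28 (16 higher, 12 lower) with values under 4 set to 4 and 35 (20 higher, 15 lower) with trend and robust variance.

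**Figure D1:**
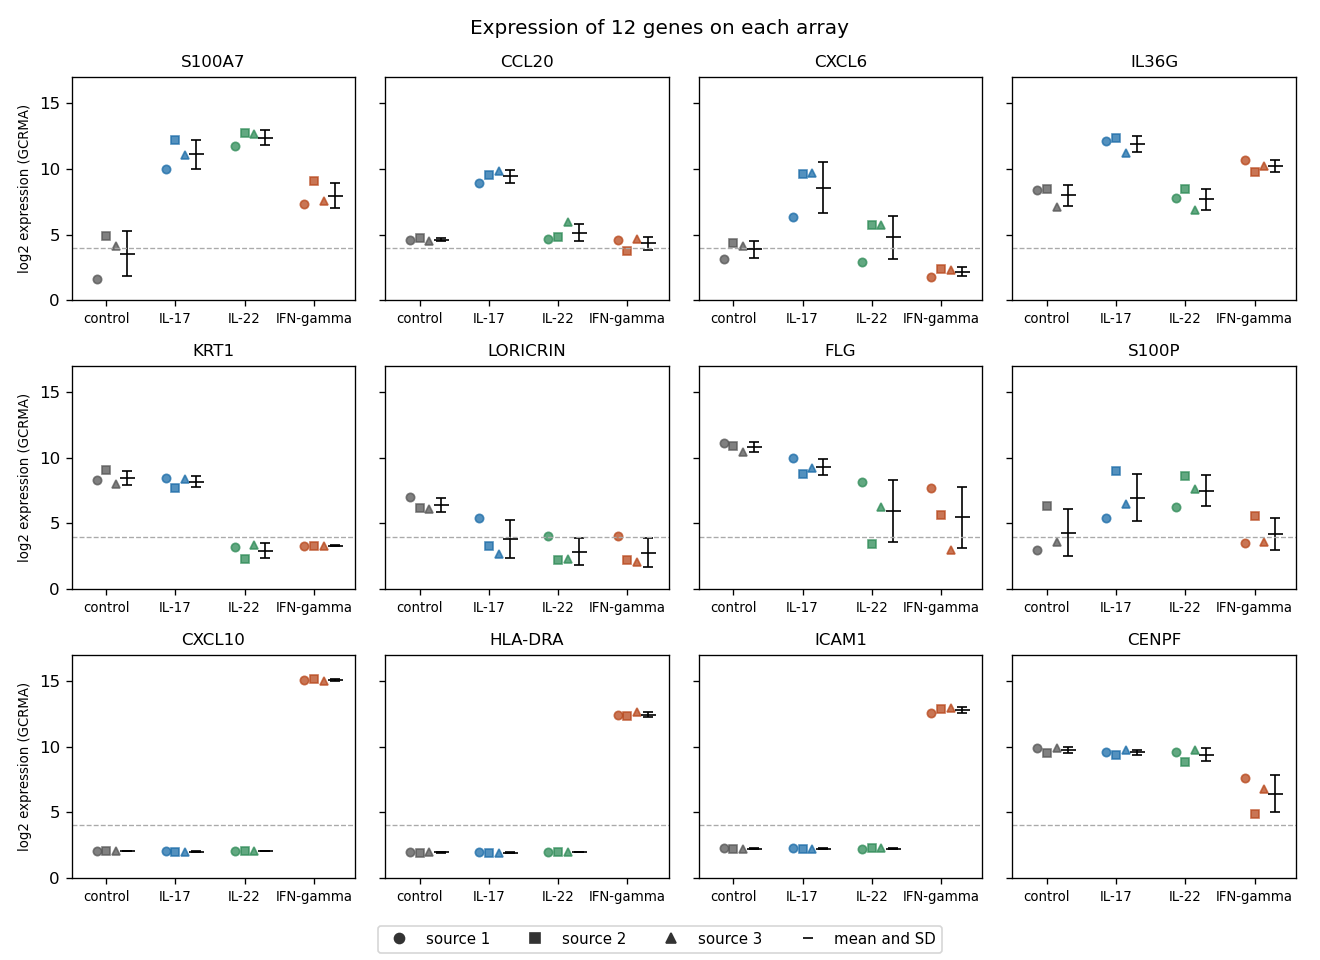
Log2 expression (vertical axis, GCRMA) of 12 genes on each of the 12 arrays, by condition (horizontal axis), with 1 symbol per keratinocyte source and the mean and SD (n = 3) in black. The dashed line marks the filter level of 4. S100A7 is at 11.11 with IL-17 and 12.38 with IL-22 against 3.54 in the control, KRT1 is at 2.93 with IL-22 and 3.31 with IFN-gamma against 8.46, and CXCL10 is at 15.05 with IFN-gamma against 2.03.

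IFN-gamma switched on chemokine, antigen presentation and interferon-stimulated genes that were at background in untreated cells. CXCL10, a ligand of the T cell receptor CXCR3, went from 2.03 ± 0.02 to 15.05 ± 0.07 (log2, SD, n = 3), at least 2120-fold (limma, adjusted p = 2.63e-13). The other CXCR3 ligands CXCL9 and CXCL11 rose at least 1510-fold and 2270-fold. HLA-DRA, an MHC class II chain, rose at least 349-fold, and the adhesion molecule ICAM1 at least 446-fold (limma, adjusted p = 2.1e-12 and 7.28e-12). KRT1 fell at least 22-fold (limma, adjusted p = 5.14e-06). FLG and the matrix glycoprotein THBS2 fell, with log2 fold changes of -5.35 ± 0.96 and -5.60 ± 0.40 (SE, n = 3; limma, adjusted p = 0.00163 and 8.33e-06), and FLG reached 4 on 2 of 3 IFN-gamma arrays.

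Every tested member rose in 4 lists: 17 of 17 IFN-gamma core genes, 9 of 9 MHC class II genes, 16 of 16 MHC class I and antigen processing genes and 28 of 28 type I interferon-stimulated genes. In these lists 10, 9, 1 and 5 members were below 4 on every control array. With such members at their lower bound the median log2 fold changes were 6.59, 7.01, 2.79 and 3.04, and the fitted medians were 8.40, 8.57, 2.79 and 3.33. The counts adjusted over the list alone were equal. Members at background in every condition without IFN-gamma entered the test only through their high IFN-gamma arrays, so the filter fixed their rise. Of 13 class II genes on the array, 9 were tested. The untested HLA-DQA1, HLA-DOA, HLA-DPB1 and HLA-DOB went from 2.32, 2.89, 2.65 and 1.95 in the control to 2.65, 2.94, 4.91 and 4.06 with IFN-gamma. The untested core gene IRF8 went from 1.94 to 2.33. CCL2, a monocyte chemokine, rose at least 274-fold, the class II invariant chain CD74 at least 180-fold and RSAD2, an antiviral enzyme, at least 230-fold. PSMB9, an immunoproteasome subunit, rose by 9.34 (at 4 or more on 2 of 3 control arrays), and the peptide transporter TAP1 by 4.32. The complement proteases C1S and C1R, at least 337-fold and 299-fold higher, and PLAAT4, a phospholipase, at least 294-fold, were also among the 10 largest rises. In the NF-kB and IL-17 response list 9 of 10 rose over all genes and adjusted over the list alone, with the complement components CFB at least 66.2-fold and C3 at least 37.5-fold higher.

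Death receptors and caspases rose in 10 of 12 cases (11 adjusted over the list alone) and 1 fell, with TNFSF10 (TRAIL, a death ligand) up by 4.82, RIPK2 by 3.02, CASP1 by 2.21 and CASP10 at least 8.87-fold. Of 7 adhesion and checkpoint molecules 4 rose, over all genes and adjusted over the list alone: ICAM1, PDCD1LG2 (PD-L2, at least 8-fold), CD40 (log2 fold change 3.15) and CD47 (1.96). In the STAT3 response list 7 of 9 rose and 1 fell, over all genes and adjusted over the list alone, with PIM1 up by 1.58 and STAT3 up by 1.20. Camera placed these 3 lists, the NF-kB list and the 4 complete ones higher, and all 8 held with an estimated correlation (adjusted p = 0.00165 to 0.0387). The filter also fixed the rise of ICAM1, PDCD1LG2 and CFB, at background in every condition without IFN-gamma. CASP10 reached 4 on 1 IL-17 array and otherwise only with IFN-gamma. Camera counts such members, all 9 tested ones for MHC class II, so its p-values are no separate support for their rise. All 8 lists were also called in each of 24 alternative settings, the fit without the filter among them.

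Proliferation genes fell with IFN-gamma. Of 35 cell cycle genes, 34 fell, over all genes and adjusted over the list alone, with a median log2 fold change of -1.03 against -0.14 over all tested genes. CENPF, a centromere protein, fell by 3.35, and the cyclins CCNE2 and CCNA2 fell by 2.06 and 1.59. The camera call for this list (adjusted p = 1.17e-11) was lost at adjusted p = 0.124 with an estimated correlation. HELLS, a chromatin remodeller of dividing cells, was at least 6.52-fold lower, and the growth factor genes PDGFA (-3.92) and WNT5A (-3.89) fell as well. CERK (-4.46), ARG1 (-4.42) and PNMA8A (-4.13) completed the 10 largest falls with DSC1 (-4.21), and ARG1 and PDGFA reached 4 on 2 of 3 IFN-gamma arrays.

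Differentiation genes moved both ways with IFN-gamma: 11 of 25 fell, led by FLG, KRT1, DSC1 and LORICRIN (-3.65), and 5 rose, over all genes and adjusted over the list alone (camera adjusted p = 0.538). Among all 6930 tested genes 2415 fell and 1216 rose, so movement both ways was not particular to this list. The antimicrobial list was higher (median 0.59, camera adjusted p = 0.0153; adjusted p = 0.358 with an estimated correlation), with 6 risers and 2 fallers in both counts. S100A7 rose by 4.42, S100A12 by 2.93 and DEFB1, a beta-defensin, by 1.98, while LCN2 fell by 0.95. Cytokine receptors and proximal signalling genes were higher (camera adjusted p = 9.9e-06; adjusted p = 0.0838 with an estimated correlation), with 10 of 15 risers in both counts. JAK2 rose at least 8.09-fold, IL1R2, a decoy receptor for IL-1, by 3.38, and the IL-22 receptor chains IL22RA1 and IL10RB by 2.14 and 1.29. The 8 tested lists without a camera call, the differentiation list included, had camera adjusted p-values between 0.167 and 0.662. Among them, 2 of 7 neutrophil chemokines rose, CXCL2 by 2.69 and CXCL1 by 1.06. CXCL6 was called lower, but its level was 3.87 ± 0.67 in the control and 2.16 ± 0.33 with IFN-gamma (log2, SD, n = 3), so no fold is given. It was called in 13 of the 21 alternative settings (limma, adjusted p = 0.000217 to 0.84), with the highest p when values under 4 were set to 4.

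For IFN-gamma, limma called 3631 of 6930 genes, 1216 higher and 2415 lower, of which 465 rose and 635 fell at least 2-fold. With each array centred on its median over the tested genes, 541 rose and 515 fell at least 2-fold. The share of falls among all called genes was 66.5%, 54.7% after this centring, 61.6% after quantile normalization and 72.5% with arrays centred on their median over all probe sets. The median log2 fold change over all tested genes was -0.142 as deposited and -0.0358, -0.107 and -0.211 in these 3 scalings. Without the filter on low values it was 0.00118, with 65.9% falls. Without the source block 2062 genes were called.

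**Figure D2:**
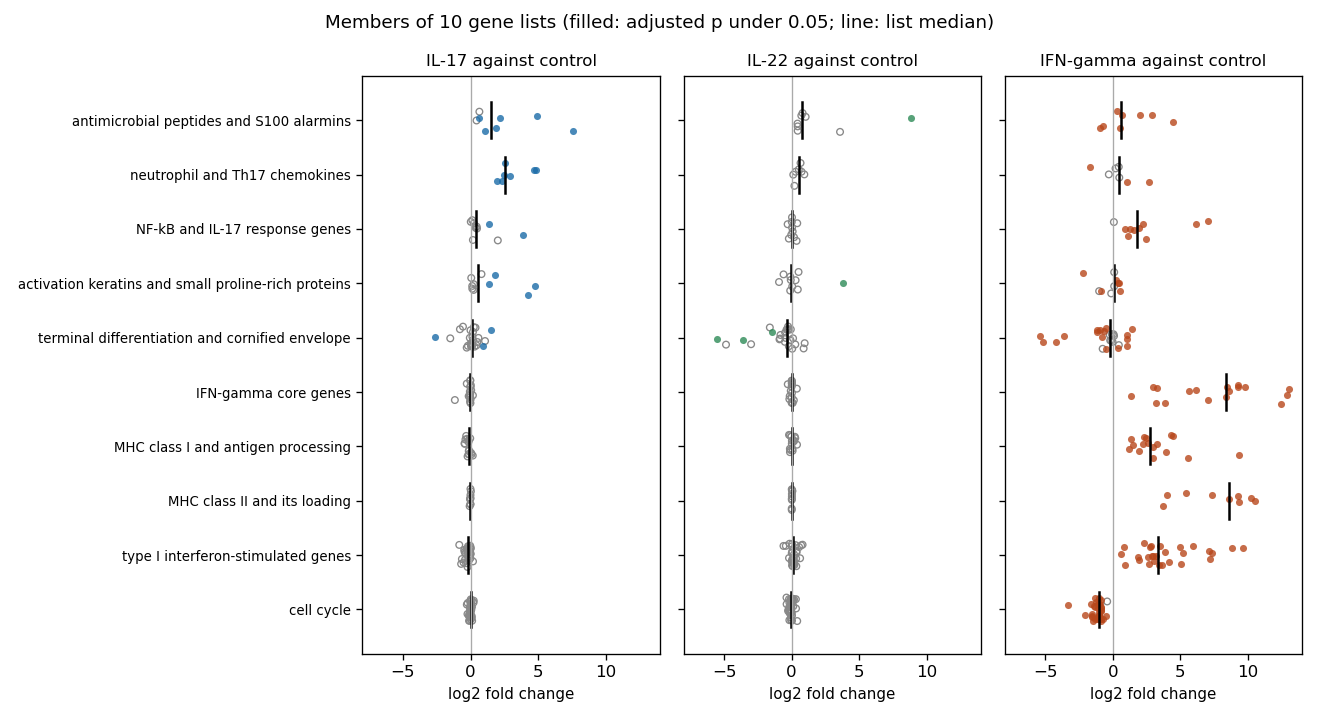
Log2 fold change against the control (horizontal axis) of the tested members of 10 gene lists (vertical axis), 1 panel per cytokine, with 1 point per gene, filled where the adjusted p was under 0.05, and a line at the list median. Fitted medians under IFN-gamma are 8.40 for IFN-gamma core genes (6.59 with genes at background at their lower bound) and -1.03 for cell cycle genes, and the IL-17 median of neutrophil and Th17 chemokines is 2.59.

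IL-17 and IL-22 differed in differentiation, activation and chemokine genes. KRT1 was at 8.17 ± 0.43 with IL-17 and 2.93 ± 0.55 with IL-22 (log2, SD, n = 3), at least 18-fold apart (limma, adjusted p = 0.000411). CCL20, IL36G and CXCL6 were higher with IL-17 by 4.30, 4.21 and 3.77 on the log2 scale, and PDZK1IP1 at least 8.3-fold. Higher with IL-22 were the gelatinase MMP9 (log2 difference -3.34 for IL-17 minus IL-22; limma, adjusted p = 0.0465), the glucose transporter SLC2A3 (-1.43), the histamine receptor HRH1 (-0.94), FLOT2 (-0.80) and CARHSP1 (-0.76). MMP9 stood at 10.50 in the control, 10.45 with IL-22 and 7.12 ± 2.15 with IL-17, and SLC2A3 at 7.74, 7.92 and 6.49 (log2, SD, n = 3). Both genes thus lay near the control with IL-22 and below it with IL-17. MMP9, FLOT2 and CARHSP1 passed in 8, 7 and 10 of the 21 alternative settings (limma, adjusted p = 0.0176 to 0.848, 0.0157 to 0.641 and 0.00863 to 0.314), and the other FLOT2 probe set stood at 0.02. SLC2A3, HRH1 and CXCL6 passed in 11, 12 and 12 settings. S100A7 did not pass this comparison (-1.28 ± 0.42, SE; limma, adjusted p = 0.279).

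Set against each other, the terminal differentiation list was higher with IL-17 than with IL-22 (5 of 25 genes, 15 adjusted over the list alone; camera adjusted p = 1.87e-14) and so was the activation list (3 of 10 genes, 6 adjusted over the list alone; camera adjusted p = 6.5e-10). Both held at adjusted p = 0.00487 with an estimated correlation. Chemokines were higher with IL-17 in 6 of 7 cases (7 adjusted over the list alone; camera adjusted p = 3.76e-15), but this call was lost with an estimated correlation, where the adjusted p was 0.05. Camera also placed NF-kB genes higher (1 of 10 genes, 4 adjusted over the list alone; adjusted p = 0.0956 with an estimated correlation) and the antimicrobial list (1 of 8 genes; 2 higher and 1 lower adjusted over the list alone; adjusted p = 0.356 with an estimated correlation). It placed the MHC class I, type I interferon, basal keratinocyte and matrix protease lists lower with IL-17 (adjusted p = 0.0956, 0.281, 0.247 and 0.247 with an estimated correlation). In these 4 lists 0, 0, 0 and 1 genes were lower, and 0, 1, 5 and 1 adjusted over the list alone. Limma called 55 genes, 49 higher and 6 lower with IL-17, of which 37 differed at least 2-fold, and 11 genes without the source block. The count was 21, 14 and 13 without source 1, 2 or 3, 32, 27 and 19 without the IL-17 array of source 1, 2 or 3, and 27 without any 1 of the IL-22 arrays. It was 30 without the filter, 31 with only the 6 arrays compared and 91 (71 higher, 20 lower) with trend and robust variance.

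IFN-gamma differed from each Th17 cytokine in many genes. Of the 42 genes raised by IL-17, however, 18 rose with IFN-gamma too and 9 fell. PDZK1IP1, for example, was at 7.05 with IL-17 and 7.06 with IFN-gamma (log2). Against IL-17, the IFN-gamma cultures had at least 2120-fold more CXCL10, while CXCL6 was at least 23.8-fold and SERPINB4 at least 19.5-fold lower, and CCL20 was lower by a log2 difference of -5.12 ± 0.30 (SE, n = 3; limma, adjusted p = 2.52e-06). THBS2 (-5.34) and ARG1 (-4.94) were lower too. Against IL-22, CXCL9, CXCL11, ICAM1 and C1S were higher with IFN-gamma by at least 1510-fold, 2270-fold, 446-fold and 337-fold, and SERPINB4 was at least 10-fold lower. S100A7 was lower by -4.42 ± 0.42 (SE, n = 3; limma, adjusted p = 4.77e-05), with THBS2 (-5.28), CERK (-4.30) and SCG5 (-4.23, at 4 or more on 1 of 3 IFN-gamma arrays). KRT1 was below 4 on every array with IFN-gamma and with IL-22, so its levels there were not compared.

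IFN-gamma core, MHC class I, MHC class II, type I interferon, adhesion and death receptor lists were higher with IFN-gamma than with either other cytokine, with an estimated correlation too (adjusted p up to 0.0284 against IL-17 and 0.0355 against IL-22). All tested members of the first 4 lists were higher against both, except 1 of the 28 type I interferon genes against IL-22, which passed adjusted over the list alone. For members of any of these lists at background in every condition without IFN-gamma, such as ICAM1 and PDCD1LG2, the filter fixed this outcome. Of 12 death receptor genes 10 were higher and 1 lower against each cytokine, and of 7 adhesion genes 4 were higher (5 higher and 1 lower against IL-17 adjusted over the list alone). Cell cycle genes were lower in 34 of 35 cases against IL-17 and 35 of 35 against IL-22, over all genes and adjusted over the list alone (adjusted p = 0.122 and 0.113 with an estimated correlation). NF-kB genes were higher against IL-17 in 8 of 10 cases and lower in 1 (adjusted p = 0.0976 with an estimated correlation) and higher in 10 of 10 against IL-22 (adjusted p = 0.0355 with an estimated correlation). STAT3 response genes and cytokine receptors were higher against both (adjusted p = 0.0976 and 0.116 against IL-17, 0.0694 and 0.0855 against IL-22, with an estimated correlation). Of 9 STAT3 response genes 5 were higher and 2 lower against IL-17 (6 and 2 adjusted over the list alone) and 4 higher against IL-22 (5 higher and 1 lower adjusted over the list alone), and of 15 cytokine receptor genes 9 were higher and 1 lower against IL-17 and 10 higher against IL-22. Chemokines were lower than with IL-17, in 6 of 7 genes over all genes and adjusted over the list alone (adjusted p = 0.345 with an estimated correlation). Limma called 3469 genes against IL-17 (68.1% lower, 54.7% after centring over the tested genes) and 3366 against IL-22 (66.3% lower, 56.3% after that centring). With arrays centred over all probe sets the shares were 76.5% and 75.8%. Without the source block the counts were 1980 and 1851, and without source 3 the count against IL-22 was 2143.

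IL-22 raised and lowered only 5 genes each, which capped its shared calls. With IL-17 it shared 3 of the raised genes and 1 of the lowered ones. S100A7, S100P and SERPINB4 rose with both, where independent lists of these sizes would share 0.0303 genes, and LORICRIN fell with both. IL-17 and IFN-gamma raised 18 genes in common, against 7.37 for independent lists, among them S100A7, S100A12, IL36G, IL1B, CXCL1, CXCL2, SLC6A14 and the intracellular sensor NOD2. Without the source block this pair shared 5 raised genes against 1.14 for independent lists, and without source 1, 2 or 3 it shared 6, 4 and 5 against 2.35, 1.23 and 1.18. Another 9 were called higher with IL-17 and lower with IFN-gamma, against 14.6 for independent lists: LCN2, PI3, SPRR3, ALOX12B, TFRC, CEP43, SLC11A2, TYW1 and CXCL6, whose mean was under 4 both in the control and with IFN-gamma. IL-22 and IFN-gamma both raised S100A7 and CARHSP1 and both lowered KRT1, CYP4B1 and LORICRIN, against 0.877 and 1.74 genes for independent lists. SCG5 rose with IL-22 and fell with IFN-gamma (-2.77), and CALML3 fell with IL-22 and rose with IFN-gamma (1.02).

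Simulated unchanged groups against the shared controls had at most 0.02 calls per direction on average and so none to share, which says nothing on how many calls of changed genes the shared controls would add. Across genes, which are not independent replicates, log2 fold changes of IL-17 and IL-22 correlated at r = 0.49, against 0.50 in the simulation. For IL-17 and IFN-gamma r was 0.149, and for IL-22 and IFN-gamma 0.266, against 0.501 in both simulations. The covariance exceeded the simulated one by 0.0291, 0.0361 and 0.0759 in these 3 pairs. With 3 control arrays the controls were not split for the calls, so part of the shared calls may come from them. Fold changes of 1 cytokine in a source and of the other in a different source share no array, and their covariance over 6 such source pairs was on average 0.0225 (-0.00331 to 0.0453) for IL-17 and IL-22, 0.0303 (0.00549 to 0.0792) for IL-17 and IFN-gamma and 0.0681 (0.0266 to 0.123) for IL-22 and IFN-gamma.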

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

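Tests of the 2-fold falls under centring, of centring over all probe sets, of the differentiation genes outside the 4 named and of leaving out 1 IL-22 array were chosen after the results were seen. Probe sets with several gene names or none entered only the alternative that tested every probe set, and no fit of genes. Of these, 6 were called for IL-17 (5 higher and 1 lower, 4 of them with several names) and 517 for IFN-gamma (161 higher, 356 lower). They were flagged as signals in data that the fits of genes did not use, and no explanation was tested.

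KRT1, FLG, DSC1 and LORICRIN were lower with IL-22 and with IFN-gamma, with a mean log2 fold change of -3.97 and -4.42 over the 4 genes when KRT1 is set at its lower bound, although FLG and DSC1 did not pass the test under IL-22. Fewer suprabasal cells in the treated cultures were predicted to lower the other differentiation genes about as much. The median of the 21 others was -0.26 with IL-22 (SD 0.63) and -0.12 with IFN-gamma (SD 0.75). That of all 25 was -0.37 (SD 1.63) and -0.23 (SD 1.85). The 4 genes were picked from this list for their large falls, so the others had to fall less under any cause. This gap therefore cannot decide on a change in cell composition. With the actin difference as a covariate the mean fall under IL-22 kept 100.1% of its size. The mean actin difference was 1.42 with IL-22 and 1.41 in the control, so the covariate could hardly move this fall. That fit therefore cannot decide on unequal RNA end coverage. A response of these 4 genes to the cytokines stays a hypothesis, found on the same 12 arrays, and other members were lower too (12 of 25 with IL-22 adjusted over the list alone). Changes in culture confluence or in mRNA stability were not testable here.

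IFN-gamma changed 52.4% of the tested genes, and 66.5% of the changed genes fell. With the actin covariate the count was 100.1% of that without it. The mean actin difference was 1.28 with IFN-gamma and 1.41 in the control. The covariate could thus move most folds only little, which makes this a weak test of unequal RNA end coverage. Scaling between arrays cannot be told apart from a broad decline as the source of the excess of falls: 54.7% of called genes fell after centring over the tested genes, which itself moves their median toward 0, 61.6% after quantile normalization, 65.9% without the filter and 72.5% after centring over all probe sets, whose median lies near background. Of the 635 genes that fell at least 2-fold, 81.1% did so after centring over the tested genes too. This centring moved the median log2 fold change only from -0.142 to -0.0358. A common shift of that size does not account for most of these falls, and a larger one was not tested. After the centring, rises of at least 2-fold outnumbered falls (541 against 515). A broad decline of transcripts beside induction of interferon genes remains a candidate explanation for the smaller falls, with scaling open.

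IL-22 had more genes than IL-17 at an unadjusted p under 0.05 (784 against 475) but fewer called genes (10 against 43). With the actin covariate the IL-22 count was 863, above 475 and above the 530 of IL-17 in the same fit. The mean actin difference was 1.42 with IL-22, 1.39 with IL-17 and 1.41 in the control, so this is a weak test of unequal RNA end coverage. Leaving out 1 IL-22 array gave 583 to 708 IL-22 genes at the unadjusted threshold and 4 to 10 called ones, while leaving out 1 IL-17 array gave 346 to 436 and 21 to 28 for IL-17, which argues against a single deviating IL-22 array as the whole cause. The excess at the unadjusted threshold varied, with 500 genes for IL-22 and 474 for IL-17 when only the 6 arrays compared were fitted, 521 and 410 without source 1, 765 and 392 without source 2, and 519 and 380 without source 3. With trend and robust variance estimates 35 genes were called for IL-22, 20 of them at least 2-fold, and 55 for IL-17. IL-22 thus still had fewer calls, and most of its calls there were not small. Many small IL-22 effects below the threshold stay a hypothesis that was not tested.

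For each of the 6 comparisons and for each of the 3 counts of genes changed at least 2-fold by a cytokine, the 6 arrays can be split in 10 ways, which is too few for a share under 0.05. In each case 1 split, the real one, gave as many genes, and the highest other split gave 0. In the other splits any real difference between the conditions enters the error. The 0 was thus close to fixed if genes truly changed, and it does not show what unchanged arrays would give. The real values were 43, 10 and 3631 genes for IL-17, IL-22 and IFN-gamma (32, 9 and 1100 at least 2-fold), 55 between IL-17 and IL-22, 3469 between IFN-gamma and IL-17, and 3366 between IFN-gamma and IL-22. Among the 10 splits, 4 part every source as the real one does, and the others put arrays of both conditions from a source on the same side.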

How the results depend on the processing

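The covariate for RNA end coverage and the centring over all probe sets were chosen after seeing the data, and the other alternatives were planned. No named gene or list that passed its test changed direction in any alternative. The IFN-gamma counts were within 1.5 times of the reported ones except where given here, and among 82 named genes changed by IFN-gamma 8 lost their call when some array or source was left out. The IL-17 and IL-22 calls were less stable: 17 of 21 and 8 of 10 named genes lost their call in at least 1 such fit, as did 7 of 10 between these cytokines. Leaving out arrays also lowers the degrees of freedom, and a condition with fewer arrays is then assumed to vary like the others.

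No replicate block, so leaving the source out of the fit, gave 11 genes for IL-17 (9 at least 2-fold), 3 for IL-22 (3 at least 2-fold), 2062 for IFN-gamma, 11 between IL-17 and IL-22, 1980 between IFN-gamma and IL-17 and 1851 between IFN-gamma and IL-22. Shared calls were then 1 for IL-17 and IL-22, 5 for IL-17 and IFN-gamma and 3 for IL-22 and IFN-gamma. The differences between sources enter the error of that fit. The fit with no filter, which tests more genes, gave 3 genes for IL-22 (3 at least 2-fold), 30 between IL-17 and IL-22, and 2 and 3 shared calls of IL-22 with IL-17 and with IFN-gamma. A stricter filter gave 23 genes for IL-22 (14 at least 2-fold) and 7 and 16 such shared calls. Values under 4 set to 4 gave 28 genes for IL-22 (18 at least 2-fold). Centring over all probe sets gave 21 (14 at least 2-fold) and 2 gene lists for IL-22. Trend and robust variance gave 35 genes for IL-22 (20 at least 2-fold) and 91 between IL-17 and IL-22. Fitting only the 6 arrays compared, with fewer degrees of freedom, gave 12 genes for IL-17 (12 at least 2-fold), 3 for IL-22 (3 at least 2-fold) and 31 between them. Testing every probe set, which counts genes more than once, gave 1734 at least 2-fold for IFN-gamma. Beyond the reasons stated, the cause was not tested.

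With an estimated correlation camera called 5 lists for IL-17, 2 for IL-22, 2 between IL-17 and IL-22 and 6 between IFN-gamma and IL-17, and fry called 2 for IL-22. Leaving out a source or an array gave 9 to 36 genes for IL-17 (9 to 29 at least 2-fold), 3 to 11 for IL-22 (3 to 9 at least 2-fold), 13 to 32 between IL-17 and IL-22, 2143 to 2998 between IFN-gamma and IL-22, and 2 to 7 lists for IL-22. Without a source, shared calls were 1 to 4 for IL-17 and IL-22, 4 to 7 for IL-17 and IFN-gamma and 2 to 4 for IL-22 and IFN-gamma. Signal over background limits the folds of genes at background in a condition, which are lower bounds, and receptor genes near the filter level such as IL17RA. Of 2166 genes with several tested probe sets, 13 had probe sets called in opposite directions for IFN-gamma and 0 for IL-17 or IL-22 in limma. For IL-17 and IL-22 only 43 and 7 probe sets were called, so the 0 was close to fixed. At an unadjusted p under 0.05, which this count did not use, there were 642 and 1106.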

Other observations

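IFN-gamma also changed members of lists that camera did not call, where 52.4% of all tested genes changed. In the immediate early and stress list 6 of 14 genes rose and 4 fell (camera adjusted p = 0.236): the stress-response regulators ATF3 (log2 fold change 2.57) and PPP1R15A (1.34) rose, while FOS (-2.72, at 4 or more on 1 of 3 IFN-gamma arrays) and EGR1 (-1.31) fell. Of 13 basal keratinocyte and hemidesmosome genes 6 fell and 1 rose, with DST at -2.35 (its 4 tested probe sets ran from -2.46 to -0.03 and 2 were called), KRT15 at -0.99 and COL7A1 at -0.74 (camera adjusted p = 0.299). The basal keratins KRT5 and KRT14 stood at -0.01 and -0.01 (limma, adjusted p = 0.898 and 0.952). Of 13 matrix protease genes 4 rose and 3 fell, 4 adjusted over the list alone (camera adjusted p = 0.662): PLAUR, the urokinase receptor, rose by 2.63 and MMP1 by 1.72, while PDGFA and ADAMTS1 (-1.74) fell. Of 18 lipid synthesis genes 13 were not called, 2 rose and 3 fell (camera adjusted p = 0.538), with ACACA at -1.02, FASN at -0.63, SCD at -0.42 and INSIG1 at 0.52. SPARC fell by 1.73, and PDGFRA, at background in the control, was at least 1.64-fold higher.

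With IL-17, MMP9 had an estimate of -3.38 ± 0.59 (SE; limma, adjusted p = 0.0502), lower in all 3 sources, and MMP1 an estimate of 1.59 ± 0.35 (SE; limma, adjusted p = 0.161). The ammonium transporter RHCG rose by 2.59, NDRG2 by 2.47, and IL36RN, the antagonist of the IL-36 receptor, by 1.02. IL36RN was at 0.85 with IFN-gamma, where it rose too, and at 0.19 with IL-22 (limma, adjusted p = 0.719). Median, mean and camera direction differed in sign for 8 lists against the control, 0 of them called: cell cycle, matrix proteases and adhesion molecules with IL-17, activation keratins and cytokine receptors with IL-22, and activation keratins, matrix proteases and lipid synthesis with IFN-gamma. The same held for 12 lists between cytokines, 0 of them called.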
